A study of Mus musculus with 9 samples.

How the data were processed

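RNA was measured in whole ventricles of male mice on a hybrid background of C57BL/6 and ICR. Per the labels' protocols, hearts were perfused with cold buffer, atria and valves were removed, RNA was extracted with Trizol, ribosomal RNA was depleted, and directional libraries were made. The 9 libraries form 3 groups of 3. Ctrl received normal chow, Ctrl_HF a high-fat diet with L-NAME for 15 weeks, and TTg_HF the same with the MGTH2A transgene. All 3 groups carried Tcf21iCre and the R26 tdTomato reporter and received tamoxifen, per the labels. That MGTH2A carries Mef2c, Gata4, Tbx5 and Hand2 is background knowledge of the mouse line.

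The deposited table has 49585 rows, each a gene symbol, and 3 columns per library. The first holds whole-number counts, called expression values per the file headers, and nothing was scaled or filtered in them. The second holds a signal that the authors called normalized expression values. Tested on the file, it is the count times 1 factor per library, within a relative deviation of 1.08e-04 for counts over 500, with a factor of 1 for TTg_HF replicate 3. How the authors chose the factors is not given in the sources used here. The third holds transformed values, which the authors made as log2 of the normalized value plus 1, within 0.005 by test on the file. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, its use of strand and the annotation are not given in the sources used here. The tests used the counts, and the authors' factors served as an alternative normalization. No column of values per library was left out of these checks.

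Of the rows 26 carried symbols that a spreadsheet had turned into dates, of which 2 names were repeated. They kept their names as deposited, so the genes behind them cannot be named here. No count was present in any library for 29540 rows. Of all row names 47121 (95.0%) were found among the symbols of GENCODE vM21 (GRCm38, the assembly of mm10), which gave the coordinates.

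Total counts ranged from 6743109 to 9364336 per library. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 12670 genes holding at least 99.9% of the counts of each library. Counts were normalised by TMM. A single quasi-likelihood model with robust estimation was fitted to the 9 libraries with group as the only term, so that the groups share 1 estimate of the spread, and the median biological coefficient of variation was 0.131. The comparisons were Ctrl_HF against Ctrl, TTg_HF against Ctrl_HF and TTg_HF against Ctrl, each by a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A rank or permutation test of 3 libraries against 3 cannot go below 0.1, so none was used for single genes. Principal components were computed from log2 CPM with a prior count of 2. R 4.3.3 was used for the statistics, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for the figures.

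Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives not called added. There were 39 lists of 6 to 40 genes: 19 of biology, 14 of cell type markers and 6 technical. Genes of the T, natural killer and B cell list were too low to be tested, which left 38 lists. Each list was tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone. Some members belong to more than 1 list, such as Des and Myl3, and the ventricle expresses most markers of the cell type lists.

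Named genes follow a rule. Mef2c, Gata4, Tbx5, Hand2, Tcf21 and Meox1 were named in any case. In Ctrl_HF against Ctrl and in TTg_HF against Ctrl_HF the 6 largest rises and the 6 largest falls were named among genes past the threshold with a mean of at least 1 CPM, replicates that did not overlap and no predicted or clone-based name. Where fewer than 6 passed, the genes of lowest unadjusted p followed as values. The 2 members of lowest p of each biology list and the 1 of lowest p of each passing cell type or technical list were added. All other genes named were chosen after their values were seen. A few genes that the rule names are not reported here.

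The share of model-responsive genes with the opposite sign in TTg_HF was set beside 50 simulations of groups with no effect, since both contrasts contain the Ctrl_HF libraries. All simulations drew the 3 groups with 1 spread per gene, shared by the groups, and no correlation between genes. The core test was tested on simulated data, in 5 simulations per comparison with 200 changed genes each. In TTg_HF against Ctrl_HF it recovered 27.1%, 66.3% and 84.1% of changes of 1.5, 2 and 3 fold, and 7.14% of its calls were false. In Ctrl_HF against Ctrl it recovered 28.6%, 65.8% and 84.0% with 7.12% false, and in TTg_HF against Ctrl 30.0%, 65.0% and 85.6% with 7.32% false. Recovery and false calls with unequal spread between groups were not tested.

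The alternatives were the size factors of DESeq2 in the edgeR fit, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 50 counts in 3 libraries, fits of the 6 libraries compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a fold of at least 1.5, and for lists the estimated correlation and fry. The authors' factors and the comparison of fold changes with no library in common were added after seeing the data. A planned change of pseudocount did not apply, since the tests used counts. With 1 library of a group left out, the remaining 2 and the other groups gave the spread.

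Whether replicate numbers pair libraries across groups is not given in the sources used here. Of 9 same-number pairs, correlations of deviations from the group mean ran from -0.164 to 0.197, with 2 over 0.1, and 1 of 9 libraries was nearest to its own number in both other groups. Libraries were therefore treated as unpaired. With the replicate block the 3 comparisons called 415, 12 and 52 genes, of which 341, 5 and 44 were among the 458, 11 and 59 called without it.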

Results

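Gene expression was measured by bulk RNA sequencing in the whole ventricle of male mice, in 3 groups of 3 libraries. Ctrl animals received normal chow. Ctrl_HF animals received a model of heart failure with preserved ejection fraction for 15 weeks, made of a high-fat diet with 60% of kilocalories from fat and of L-NAME, an inhibitor of nitric oxide synthase, at 1 g/L in the drinking water. TTg_HF animals received the same model and carried the MGTH2A transgene, which joins the cardiac transcription factors Mef2c, Gata4, Tbx5 and Hand2 by 2A peptides. A tamoxifen-inducible Cre recombinase expressed from Tcf21, a gene of the fibroblast lineage, acted on a tdTomato reporter and, in TTg_HF, on the transgene. Tamoxifen was given at 2 mg per day for 5 days at week 5. The series title names cardiac reprogramming and Gata4 overexpression as its subject. No transgenic animals on normal chow were analysed here, so TTg_HF differed from Ctrl in both diet and genotype.

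Total counts were 7951901, 8852515 and 8553124 in Ctrl replicates 1, 2 and 3, 7204862, 7061412 and 8840145 in Ctrl_HF, and 6743109, 9364336 and 8419712 in TTg_HF. At that depth 1 count was worth 0.107 to 0.148 CPM (counts scaled to a common library total), and 12670 genes were tested. Expression is given as CPM after TMM normalisation, as mean ± SD over the 3 libraries of a group (n = 3). Fold changes are log2 values with a standard error (SE). The SE was derived from the F test, as the absolute log2 fold change divided by the square root of F. Adjusted p-values of single genes come from edgeR, and those of gene lists from camera with a preset correlation. The labels number the replicates without stating that each came from a separate animal, so the p-values rest on the spread between these libraries. In a principal component analysis the first component held 31.2% of the variance. Ctrl_HF replicates 2 and 3 lay at 48.5 and 23.5 on it, Ctrl_HF replicate 1 at 5.12, and the 6 libraries of the other groups between -23.5 and -2.33.

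The genes of the transgene were examined first, since they test the group labels. Tbx5, a T-box factor of the developing heart, was at 144 ± 43.4 CPM in TTg_HF, against 23.7 ± 3.46 in Ctrl_HF and 28.9 ± 2.70 in Ctrl (n = 3 each). It rose against Ctrl_HF by a log2 fold change of 2.6, SE 0.21 (adjusted p = 0.00253 by edgeR), and the lowest TTg_HF library, at 103 CPM, lay above all 6 others. Mef2c, a MADS-box factor, was at 167 ± 33.5 CPM in TTg_HF and 98.9 ± 7.503 in Ctrl_HF, with a log2 fold change that missed the threshold (0.75, SE 0.13, adjusted p = 0.0635). Gata4, a zinc-finger factor, was at 214 ± 23.3 and 143 ± 4.44 CPM in the same groups (0.59, SE 0.12, adjusted p = 0.0940), and Hand2, a basic helix-loop-helix factor, at 19.4 ± 0.864 and 13.2 ± 1.95 (0.55, SE 0.19, adjusted p = 0.216). For each of the 4 factors the 3 TTg_HF libraries lay above all 6 libraries of the other groups, and chance puts 3 libraries above 6 others in 1.19% of cases. Tcf21, the driver gene, was at 3.50 ± 0.890, 4.13 ± 0.560 and 4.35 ± 0.125 CPM in Ctrl, Ctrl_HF and TTg_HF, with no comparison past the threshold. Counts per gene symbol do not separate transgene reads from endogenous reads. In a fit of the 6 libraries of Ctrl_HF and TTg_HF alone Tbx5 had an adjusted p of 0.0600, the highest of its 17 alternatives (lowest 4.94e-30). Mef2c and Gata4 passed without Ctrl_HF replicate 1 (adjusted p = 0.0180 and 0.0356), Mef2c also without TTg_HF replicate 1 (0.0362), and both passed in DESeq2 (8.03e-05 and 0.00278, against a highest value over all alternatives of 0.201 and 0.331).

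**Figure D1:**
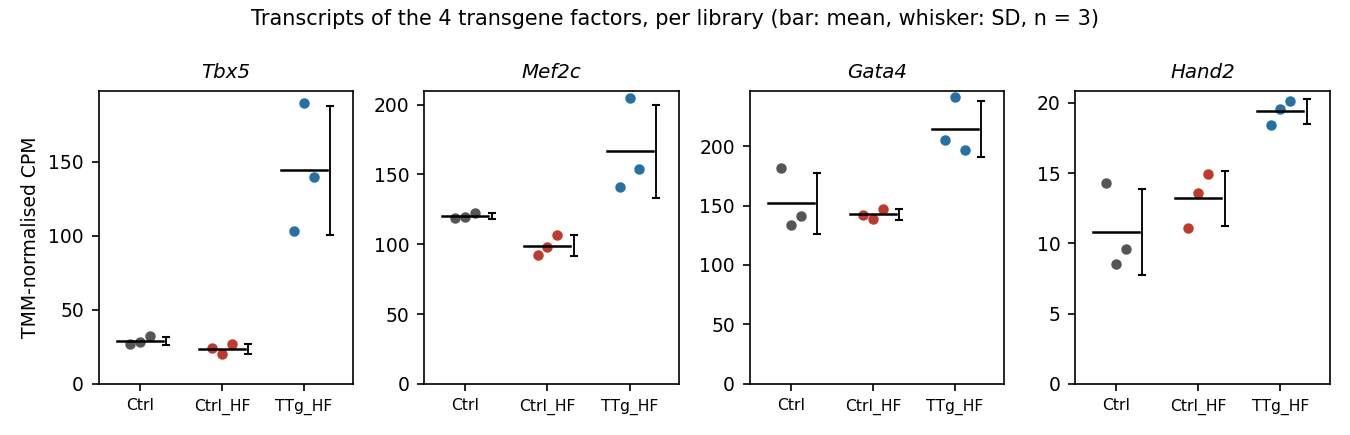
TMM-normalised CPM of Tbx5, Mef2c, Gata4 and Hand2 in each of the 9 libraries of Ctrl, Ctrl_HF and TTg_HF, on linear axes from 0, with the bar at the group mean and the whisker at 1 SD (n = 3). Tbx5 was at 103 to 189.5 CPM in the TTg_HF libraries and at 20.2 to 32.0 in the other 6.

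The first comparison, Ctrl_HF against Ctrl, shows what differed with the diet and L-NAME in animals without the transgene. Pdk4, the kinase that shuts off pyruvate dehydrogenase, went from 542 ± 100.1 to 2821 ± 915 CPM (2.38, SE 0.27, adjusted p = 0.00845). Ankrd1, a nuclear and sarcomeric protein induced by cardiac stress, rose from 1276 ± 105 to 3472 ± 882 CPM (1.44, SE 0.16, adjusted p = 0.00680). Lox, the enzyme that crosslinks collagen and elastin, rose from 5.74 ± 0.574 to 22.8 ± 4.67 (1.99, SE 0.28, adjusted p = 0.00800). Ky, a muscle protein needed for normal muscle growth, fell from 39.6 ± 2.74 to 6.00 ± 0.298 CPM (-2.72, SE 0.15, adjusted p = 1.51e-05). Abat, the transaminase that breaks down GABA, fell from 63.5 ± 7.77 to 9.72 ± 1.33 (-2.71, SE 0.22, adjusted p = 6.97e-04). The other genes with the largest falls were Ptchd3 (-2.52), Pla2g2d (-2.11), Foxo6 (-2.04) and the myosin light chain kinase gene Mylk4 (-1.88). Pla2g2d passed in 9 of its 16 alternatives (adjusted p 0.00485 to 0.0946) and was lost without Ctrl replicates 1, 2 and 3 (0.0634, 0.0712 and 0.0946), Ctrl_HF replicates 2 and 3 (0.0695 and 0.0939) and TTg_HF replicate 2 (0.0545). Foxo6 was lost without Ctrl replicate 2 (0.0827) and Ctrl_HF replicate 3 (0.0658), and Ptchd3 without Ctrl replicate 3 (0.0534). Of 12670 genes, 227 rose and 231 fell at an adjusted p under 0.05, and 2614 had an unadjusted p under 0.05. The total of 458 depended on single libraries: it was 293, 85 and 142 without Ctrl replicates 1, 2 and 3, 1122, 257 and 152 without Ctrl_HF replicates 1, 2 and 3, and 224 and 304 without TTg_HF replicates 2 and 3. A fit of the 6 libraries of Ctrl and Ctrl_HF alone called 126.

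**Figure D2:**
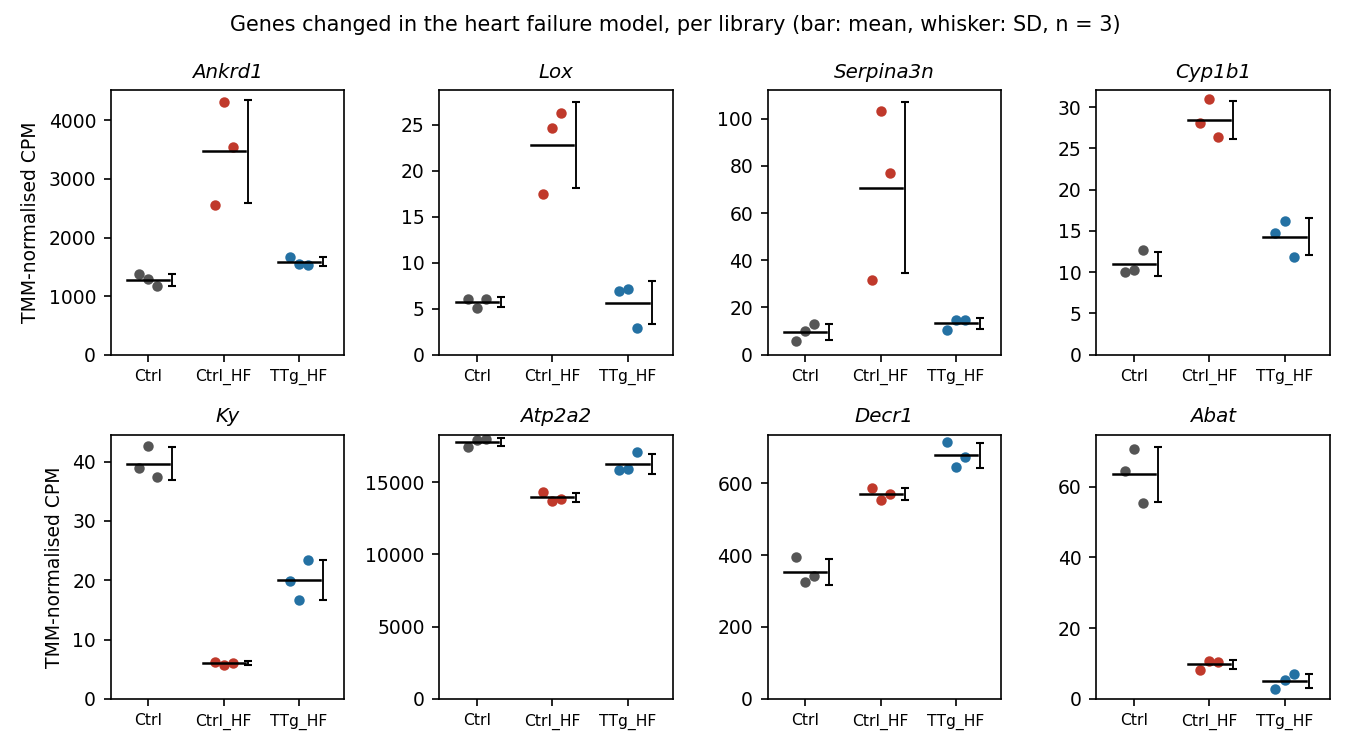
TMM-normalised CPM of 8 genes in each library of Ctrl, Ctrl_HF and TTg_HF, on linear axes from 0, with the bar at the group mean and the whisker at 1 SD (n = 3). Ankrd1, Lox, Serpina3n and Cyp1b1 had their highest mean in Ctrl_HF, Ky and Atp2a2 their lowest, while Decr1 was at 569.9 CPM in Ctrl_HF and 677 in TTg_HF, and Abat at 9.72 and 5.02.

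Fuel handling genes changed in both directions. In the list of fatty acid oxidation genes and targets of PPAR, the fatty acid sensing nuclear receptors, 13 of 32 measured members rose and 1 fell over all genes. In it 22 rose and 2 fell adjusted over the list alone (camera adjusted p = 2.19e-12, and adjusted p = 0.130 with an estimated correlation). Beside Pdk4 the risers included Decr1 (0.69), the carnitine-acylcarnitine carrier Slc25a20 (0.61), Ech1 (0.48) and the fatty acid binding protein Fabp3 (0.38). The acyl-CoA thioesterases Acot1 (2.22) and Acot2 (1.21) also rose, though their similar sequences can share reads. Lpl, the lipase that frees fatty acids from lipoproteins, fell from 5046 ± 58.8 to 3472 ± 199 CPM (-0.54, SE 0.06, adjusted p = 0.00342). Of the 20 genes of ketone and branched-chain amino acid catabolism 11 fell over all genes and 14 adjusted over the list alone (camera adjusted p = 4.84e-12, and adjusted p = 0.187 with an estimated correlation). Bdh1, which oxidises the ketone body β-hydroxybutyrate, fell from 302 ± 32.2 to 145 ± 6.69 CPM (-1.06, SE 0.11, adjusted p = 0.00286), and Ppm1k, the phosphatase that activates branched-chain ketoacid dehydrogenase, from 41.9 ± 4.81 to 18.9 ± 2.33 (-1.15, SE 0.13, adjusted p = 0.00342).

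Glucose uptake and glycolysis was lower as a list (camera adjusted p = 0.00603, and adjusted p = 0.324 with an estimated correlation). Its 4 of 27 members that fell over all genes were the insulin-responsive glucose transporter gene Slc2a4 (-0.74), Pdp1 (-0.59), the muscle enolase gene Eno3 (-0.59) and the hexokinase gene Hk2 (-0.37), and adjusted over the list alone 6 were lower and 1 higher. Nuclear-encoded oxidative phosphorylation had a median of -0.14 over 40 members (camera adjusted p = 1.37e-07, and adjusted p = 0.268 with an estimated correlation), with 1 lower over all genes, the ATP synthase gene Atp5o (-0.28), and 15 adjusted over the list alone. Without Ctrl replicate 2 Slc2a4, Eno3 and Atp5o had adjusted p of 0.0998, 0.0508 and 0.161, and Atp5o passed in 6 of its 17 alternatives (adjusted p 0.00578 to 0.161). Slc2a4 was also lost without Ctrl replicate 3 (0.0776) and Ctrl_HF replicate 3 (0.0838), and Atp5o without Ctrl replicates 1 and 3 (0.0786 and 0.124), Ctrl_HF replicates 2 and 3 (0.0573 and 0.132) and TTg_HF replicates 1, 2 and 3 (0.0599, 0.0836 and 0.0769).

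Matrix and fibroblast genes were higher in Ctrl_HF as lists. Collagens had a median of 0.65 over 18 members (camera adjusted p = 4.10e-06, and adjusted p = 0.272 with an estimated correlation). Only Col16a1 passed over all genes, from 6.86 ± 0.486 to 11.8 ± 1.46 CPM (0.78, SE 0.16, adjusted p = 0.0270), and 8 rose adjusted over the list alone. Col1a1, the main fibrillar collagen, was at 142 ± 40.8 and 221 ± 10.1 CPM (0.64, SE 0.19, adjusted p = 0.108), and Col12a1 had a fold change of 1.35 (adjusted p = 0.0782). Among other matrix and crosslinking genes 5 of 31 rose over all genes, namely Lox, the elastin crosslinking gene Loxl1 (0.87), Eln (0.75), Fbln2 (0.57) and Bgn (0.56), and 10 adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.187 with an estimated correlation). The activated fibroblast list had 4 of 17 members higher and 1 lower over all genes, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.50e-05, and adjusted p = 0.187 with an estimated correlation). Tgfb2, a growth factor of fibrosis, rose from 14.1 ± 3.12 to 34.0 ± 4.17 CPM (1.27, SE 0.18, adjusted p = 0.00680), and the matricellular protein gene Thbs4 from 9.32 ± 1.46 to 30.2 ± 12.01 (1.69, SE 0.28, adjusted p = 0.0135).

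Aebp1 (0.73) and Runx1 (1.06) were the other risers of that list, and Lrrc15 (-1.52), a surface protein of myofibroblasts, fell. Meox1, a regulator of fibroblast activation, was at 9.18 ± 2.33 and 21.2 ± 6.85 CPM (1.21, SE 0.35, adjusted p = 0.09996), and the matricellular gene Postn at 30.6 and 67.8 (adjusted p = 0.103). Resting fibroblast identity was higher as a list (camera adjusted p = 0.0148, and adjusted p = 0.272 with an estimated correlation), with 1 of 15 members higher over all genes, Medag (0.70), and 4 adjusted over the list alone, among them Pi16 (0.54, adjusted p = 0.0820). Without Ctrl replicate 2 Col16a1, Fbln2, Thbs4 and Medag had adjusted p of 0.0866, 0.0534, 0.0777 and 0.192. Col16a1 was also lost without Ctrl replicates 1 and 3 (0.0668 and 0.0883) and Ctrl_HF replicates 2 and 3 (0.0722 and 0.0813), Thbs4 without Ctrl replicate 3 (0.0644), and Medag without Ctrl replicates 1 and 3 (0.106 and 0.0795), Ctrl_HF replicates 2 and 3 (0.125 and 0.140) and TTg_HF replicates 1, 2 and 3 (0.0680, 0.0769 and 0.0627). Without Ctrl_HF replicate 1 the resting fibroblast list had a camera adjusted p of 0.250, the highest of its 17 alternatives with the preset correlation.

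Cardiomyocyte genes differed by function. The stress and fetal program was higher, with a median of 1.38 over 14 members (camera adjusted p = 2.86e-07, and adjusted p = 0.187 with an estimated correlation). Ankrd1 and the stress cytokine gene Gdf15 (1.64, SE 0.29, adjusted p = 0.0152) rose over all genes and 11 members adjusted over the list alone, while the natriuretic peptide gene Nppb was at 206 ± 67.7 and 562 ± 279 CPM (1.45, SE 0.56, adjusted p = 0.208). Calcium handling and ion channel genes were lower, 5 of 24 over all genes and 11 adjusted over the list alone (camera adjusted p = 1.01e-07, and adjusted p = 0.0756 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 17783 ± 284 to 13962 ± 327 CPM (-0.35, SE 0.05, adjusted p = 0.00772), and Kcnip2, a subunit of the transient outward potassium channel, from 179 ± 27.7 to 88.6 ± 18.4 (-1.02, SE 0.15, adjusted p = 0.00860). The potassium channel genes Kcnh2 (-1.03), Kcnq1 (-0.64) and Kcnj11 (-0.42) fell as well. In the sarcomere list 4 of 22 members fell, among them Mybpc3 (-0.41) and Myl3 (-0.41), the intermediate filament gene Des rose (0.60), and adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 0.00125, and adjusted p = 0.187 with an estimated correlation). Myocd, a coactivator of serum response factor, fell from 160.4 ± 26.6 to 85.9 ± 10.9 CPM (-0.90, SE 0.13, adjusted p = 0.00860). With Irx4 (-0.60), a ventricular factor, it made up the 2 of 15 other cardiac transcription factors that fell over all genes and adjusted over the list alone (camera adjusted p = 0.192). Without Ctrl replicate 2 Gdf15, Des, Mybpc3 and Irx4 had adjusted p of 0.0732, 0.0647, 0.0750 and 0.0999. Calls were also lost for Gdf15 without Ctrl replicate 3 (0.0673), for Mybpc3 without Ctrl replicate 3 (0.0634), and for Irx4 without Ctrl replicates 1 and 3 (0.0748 and 0.0761), Ctrl_HF replicate 2 (0.0748) and TTg_HF replicate 2 (0.0549).

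Inflammatory genes were among the largest rises. Lcn2, an acute-phase protein that binds bacterial siderophores, was at 2.17 ± 0.273 CPM in Ctrl and 28.5 ± 19.4 in Ctrl_HF (3.71, SE 0.74, adjusted p = 0.0412). Spp1, which encodes osteopontin, was at 0.671 ± 0.130 and 5.74 ± 4.26 (3.06, SE 0.57, adjusted p = 0.0210), and the protease inhibitor gene Serpina3n was at 9.54 ± 3.43 and 70.7 ± 36.3 (2.88, SE 0.46, adjusted p = 0.0219). The receptor gene Gpr35 (3.05) also rose. In the list of cytokines, chemokines and adhesion molecules 5 of 26 rose over all genes (Lcn2, Spp1, Ccl9 1.76, Icam1 0.87 and Vcam1 0.78) and 15 adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.187 with an estimated correlation). The Ctrl_HF libraries carried these rises unevenly: Lcn2 was at 6.15 CPM in replicate 1 and at 40.6 and 38.8 in replicates 2 and 3, which stood apart on the first principal component, and Spp1 at 2.32, 10.5 and 4.40. Lcn2 lost its call without Ctrl replicates 1, 2 and 3 (adjusted p = 0.107, 0.170 and 0.132), Ctrl_HF replicates 2 and 3 (0.102 and 0.0915) and TTg_HF replicates 1, 2 and 3 (0.0648, 0.0813 and 0.0626), with a range over its alternatives of 2.58e-05 to 0.217. Without Ctrl replicates 1, 2 and 3 Spp1 had 0.0638, 0.104 and 0.0724 and Serpina3n 0.0623, 0.105 and 0.0634, and Serpina3n had 0.0583 without Ctrl_HF replicate 3. Gpr35 was lost without Ctrl replicates 2 and 3 (0.0714 and 0.0617), and Vcam1 without Ctrl replicates 2 and 3 (0.132 and 0.0890) and Ctrl_HF replicates 2 and 3 (0.0740 and 0.0519).

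Of the other biology lists, oxidative stress and NRF2 targets was higher (camera adjusted p = 0.00731, and adjusted p = 0.187 with an estimated correlation). Over all genes 4 of 24 members rose, the catalase gene Cat (0.67), Ucp2 (0.71), the heme oxygenase gene Hmox1 (1.19) and the sulfiredoxin gene Srxn1 (1.32), and 8 adjusted over the list alone. The endoplasmic reticulum stress list was higher (camera adjusted p = 0.00731, and adjusted p = 0.337 with an estimated correlation). Its 2 of 21 called members, over all genes and adjusted over the list alone, were Atf4 (0.93, SE 0.16, adjusted p = 0.0154), a transcription factor of amino acid and stress responses, and its target Asns (1.53, SE 0.27, adjusted p = 0.0156). Interferon response was higher (camera adjusted p = 0.00208, and adjusted p = 0.497 with an estimated correlation), with 1 of 22 members up over all genes, Oas2 (1.15), and 3 adjusted over the list alone, among them Irf9 (0.71, adjusted p = 0.0802). Of 18 genes of nitric oxide and cyclic GMP signalling, the pathway that L-NAME acts on, only the cyclic GMP-dependent kinase gene Prkg1 rose (0.57, SE 0.11, adjusted p = 0.0249), also adjusted over the list alone, and Nos2 was at -0.79 (adjusted p = 0.108). That list had a median of 0.03, a mean of -0.04 and a camera adjusted p of 0.724. Sterol and fatty acid synthesis (28 members, adjusted p = 0.359) had no member past the threshold over all genes by edgeR, and 1 higher and 1 lower adjusted over the list alone, Me1 (0.42) and Scd2 (-0.56). Cell cycle had a median of 0.04 and a mean of -0.11 (camera adjusted p = 0.344), with Mcm2 (-0.99) alone past the threshold adjusted over the list alone. Camera calls were lost for interferon response without Ctrl replicate 1 (0.0862) and Ctrl_HF replicate 1 (0.606), for oxidative stress without Ctrl_HF replicate 1 (0.110), and for endoplasmic reticulum stress without Ctrl replicate 2 (0.128). Prkg1 passed in 12 of its 17 alternatives (adjusted p 0.00399 to 0.0921) and was lost without Ctrl replicates 2 and 3 (0.0921 and 0.0893) and Ctrl_HF replicates 2 and 3 (0.0637 and 0.0729). Atf4 was lost without Ctrl replicates 2 and 3 (0.0732 and 0.0679), Asns without Ctrl replicate 2 (0.0726) and Ctrl_HF replicate 3 (0.0583), Cat without Ctrl replicates 2 and 3 (0.0522 and 0.0546), Srxn1 without Ctrl replicate 3 (0.0534), and Oas2 without Ctrl replicate 2 (0.0508).

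Markers of cell types differed beside these groups. The macrophage list was higher with a median of 0.53 over 17 members (camera adjusted p = 6.58e-04, and adjusted p = 0.268 with an estimated correlation). Mrc1 (0.84, SE 0.11, adjusted p = 0.00680), C1qb (0.62) and the monocyte receptor gene Ccr2 (1.52) rose over all genes, and 5 adjusted over the list alone. Ventricular cardiomyocyte markers were lower with a median of -0.27 over 14 members (camera adjusted p = 6.58e-05, and adjusted p = 0.268 with an estimated correlation), 2 lower and 1 higher over all genes and 9 lower and 1 higher adjusted over the list alone. Endothelial (median 0.18), epicardial and mesothelial (0.67) and adipocyte (0.43) lists were higher with camera adjusted p of 0.0423, 0.00968 and 0.0148, and adjusted p of 0.382, 0.187 and 0.268 with an estimated correlation. Members higher over all genes were 0 of 15, 0 of 4 and 2 of 5. Adjusted over the list alone 3, 2 and 3 were higher, and 1 adipocyte member lower. The lowest-p members were Eng (0.48, adjusted p = 0.0625), Aldh1a2 (3.10, 0.0767) and Cidea (0.82, 0.0122). Camera calls were lost without Ctrl_HF replicate 1 for macrophages (0.0810), without Ctrl replicate 1 for adipocytes (0.101), and without Ctrl replicate 1 and Ctrl_HF replicates 2 and 3 for endothelium (0.188, 0.0744 and 0.0654). The endothelial median was 0.11 without Ctrl_HF replicate 2, and the epicardial median 1.40 without Ctrl replicate 1. With no filter the adipocyte list reversed to a median of -0.76 (adjusted p = 0.532). Cidea was lost without Ctrl replicate 2 (0.0712).

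Among the technical lists, heat shock (median 0.47, camera adjusted p = 0.00156) and cytoplasmic ribosomal proteins (0.21, 2.86e-07) were higher, with adjusted p of 0.324 and 0.324 with an estimated correlation. Neither had a member past the threshold over all genes by edgeR (lowest adjusted p 0.0650 for Cryab and 0.0501 for Rpl3), and 1 and 2 passed adjusted over the list alone. The heat shock median was 0.23 without Ctrl replicate 2. The chaperone gene Hspb1 was at 200.2 CPM in Ctrl_HF replicate 1 and at 971 and 625 in replicates 2 and 3. The remaining lists did not pass camera. Their adjusted p was 0.205 for smooth muscle, 0.142 for pericytes, 0.142 for lymphatic endothelium, 0.986 for atrial cardiomyocytes and 0.933 for Schwann cells and nerve. It was 0.205 for neutrophils and mast cells, 0.0808 for erythroid cells, 0.287 for skeletal muscle, 0.505 for immediate early genes, 0.105 for the circadian clock, 0.142 for mitochondrially encoded genes and 0.287 for the sex chromosome genes. In the clock list 3 of 18 genes fell over all genes and 5 adjusted over the list alone. Clock (0.0294), lymphatic (0.0347) and pericyte (0.0445) lists passed without Ctrl_HF replicate 2, immediate early genes without Ctrl_HF replicate 3 (0.0125), mitochondrially encoded genes without Ctrl replicate 2 (0.00189), and erythroid genes without Ctrl replicate 2 (0.0272) and TTg_HF replicates 1 and 2 (0.0144 and 0.00597).

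The second comparison, TTg_HF against Ctrl_HF, asks what differed with the transgene within the model. Beside Tbx5, 5 genes rose and 5 fell. Ky, which had fallen in the model, rose from 6.00 ± 0.298 to 20.02 ± 3.35 CPM (1.73, SE 0.15, adjusted p = 0.00217). Scn4a, the skeletal muscle sodium channel gene, rose from 41.9 ± 9.25 to 105 ± 12.02 CPM (1.33, SE 0.17, adjusted p = 0.0304). Papln, an extracellular matrix glycoprotein gene, rose from 13.4 ± 2.58 to 31.9 ± 3.89 (1.24, SE 0.17, adjusted p = 0.0304). Mlf1 rose from 34.3 ± 4.42 to 70.0 ± 13.8 (1.03, SE 0.15, adjusted p = 0.0369) and the phosphatase gene Ptp4a3 from 209.9 ± 0.604 to 332 ± 30.2 (0.66, SE 0.08, adjusted p = 0.0179). Lox fell from 22.8 ± 4.67 to 5.65 ± 2.37 CPM (-2.02, SE 0.28, adjusted p = 0.0345), against a Ctrl mean of 5.74. Cyp1b1, a cytochrome P450 gene, fell from 28.5 ± 2.32 to 14.3 ± 2.23 CPM (-0.99, SE 0.15, adjusted p = 0.0369), and Slc7a1, a transporter of cationic amino acids, from 83.5 ± 10.7 to 46.6 ± 1.72 (-0.84, SE 0.12, adjusted p = 0.0345). The remaining falls were in the noncoding transcript AA465934, from 19.1 ± 7.42 to 1.78 ± 0.632 CPM (-3.45, SE 0.39, adjusted p = 0.0227), and in Myo19, a mitochondrial myosin gene, from 17.7 ± 3.68 to 6.82 ± 0.647 (-1.38, SE 0.21, adjusted p = 0.0369).

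These 11 genes were all that passed in edgeR among 12670, while 1807 had an unadjusted p under 0.05. Simulated 2-fold changes were recovered in 66.3% of cases, but with 1 spread shared by all groups. The real Ctrl_HF libraries differed more from each other, so real changes of that size may be missed more often. A spread shared with tighter groups can also be too small for contrasts that contain Ctrl_HF, so that too many genes pass. Fits of the 6 libraries compared called 126 rather than 458 genes in Ctrl_HF against Ctrl, and 117 rather than 59 in TTg_HF against Ctrl. In TTg_HF against Ctrl_HF such a fit called 0. DESeq2 called 339 genes, among them all 11, and limma-voom 8 of the 11. The count was 5 without Ctrl replicate 2, 665, 18 and 3 without Ctrl_HF replicates 1, 2 and 3, and 26, 2 and 5 without TTg_HF replicates 1, 2 and 3. Tbx5 and Ky kept their calls in 16 and 16 of 17 alternatives, and in the fit of the 6 libraries alone both had an adjusted p of 0.0600. Without TTg_HF replicate 2 the 9 others had adjusted p from 0.132 to 0.172, and without Ctrl_HF replicate 3 Tbx5, Ky and Slc7a1 were the genes left. Other single libraries whose loss ended a call were, for Lox, Ctrl replicates 1, 2 and 3 (0.0503, 0.0718 and 0.0647) and Ctrl_HF replicate 2 (0.0662), for Cyp1b1, Ctrl replicates 1 and 2 (0.0503 and 0.0718), Ctrl_HF replicate 2 (0.0662) and TTg_HF replicates 1 and 3 (0.0626 and 0.201), for Slc7a1, Ctrl_HF replicate 2 (0.0581) and TTg_HF replicate 3 (0.201), and for Mlf1, Ctrl replicates 1, 2 and 3 (0.0628, 0.0718 and 0.0514) and TTg_HF replicate 3 (0.195). For Scn4a they were Ctrl replicate 2 (0.0625), Ctrl_HF replicate 2 (0.0699) and TTg_HF replicate 3 (0.121), for Papln Ctrl replicate 2 (0.0615) and TTg_HF replicate 3 (0.0731), for AA465934 Ctrl replicate 2 (0.0545) and TTg_HF replicate 3 (0.0956), and for Myo19 Ctrl replicate 3 (0.0704) and TTg_HF replicates 1 and 3 (0.0620 and 0.201). Gfod1 (-0.75) and Ankrd1 (-1.13) missed the threshold with adjusted p of 0.0508 and 0.0508.

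Stress, inflammatory and activated fibroblast genes were lower with the transgene as lists. The cardiomyocyte stress and fetal list had a median of -1.05 over 14 members, none past the threshold over all genes by edgeR and 11 lower adjusted over the list alone (camera adjusted p = 8.92e-10, and adjusted p = 0.351 with an estimated correlation). Ankrd1 was at 3472 ± 882 CPM in Ctrl_HF and 1584 ± 79.1 in TTg_HF. Xirp1, an actin-binding protein gene of intercalated discs, was at 72.3 ± 31.8 and 21.2 ± 8.69 (-1.78, SE 0.44, adjusted p = 0.161), and Nppb at 562 ± 279 and 152 ± 88.7 (-1.89, SE 0.57, adjusted p = 0.216). Inflammatory genes had a median of -1.08 over 26 members, none past the threshold over all genes by edgeR and 9 lower adjusted over the list alone (camera adjusted p = 1.01e-06, and adjusted p = 0.375 with an estimated correlation). Lcn2 was at 2.63 ± 1.42 CPM in TTg_HF (-3.41, SE 0.72, adjusted p = 0.1195), and the neutrophil protein gene S100a9 at 0.767 ± 0.156 against 3.31 ± 0.238 in Ctrl_HF (-2.10, SE 0.47, adjusted p = 0.108). Activated fibroblast genes had a median of -0.31 over 17 members (camera adjusted p = 0.0148, and adjusted p = 0.375 with an estimated correlation), with none past the threshold over all genes by edgeR and 1 higher and 3 lower adjusted over the list alone. Thbs4 was at 9.36 ± 1.83 CPM in TTg_HF (-1.70, SE 0.28, adjusted p = 0.0720), Lrrc15 at 28.6 ± 5.37 (1.52, SE 0.28, adjusted p = 0.0940), and Meox1 at 11.9 ± 5.22 (-0.85, SE 0.35, adjusted p = 0.321). Without TTg_HF replicate 3 the activated fibroblast list had a camera adjusted p of 0.0627 (highest of its 17 alternatives with the preset correlation 0.0683) and a median of -0.12. Its median was -0.47 without Ctrl_HF replicate 2 and -0.47 without TTg_HF replicate 1. Through Ctrl_HF replicate 1 alone, against TTg_HF, it was -0.04, and through replicates 2 and 3, which stood apart on the first principal component, -0.46 and -0.37. In the same way the stress median was -0.47, -1.49 and -1.20 and the inflammatory median -0.69, -1.45 and -0.67 through replicates 1, 2 and 3. The inflammatory median was -0.66 without Ctrl_HF replicate 2.

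Collagens did not pass camera with the transgene (adjusted p = 0.864), with a median of 0.08, a mean of -0.12 and no member past the threshold over all genes by edgeR or adjusted over the list alone. Through Ctrl_HF replicates 1, 2 and 3 alone, against TTg_HF, the collagen median was 0.124, -0.248 and 0.015. Col1a1 was at 221 ± 10.1 CPM in Ctrl_HF and 241 ± 40.8 in TTg_HF (0.12, SE 0.19, adjusted p = 0.817), Col14a1 had a fold change of 0.85 and Col12a1 of -1.23 (adjusted p = 0.176 and 0.186). In the other matrix and crosslinking list Lox alone fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0570). That list passed camera without Ctrl replicate 2 (0.0400), Ctrl_HF replicate 1 (0.0231) and TTg_HF replicates 1 and 2 (0.0118 and 0.0475), with a highest adjusted p of 0.221 over its alternatives with the preset correlation and of 0.695 with an estimated correlation. Resting fibroblast identity did not pass (adjusted p = 0.836), with 1 member higher and 2 lower adjusted over the list alone.

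Fatty acid oxidation (median 0.11 over 32 members), calcium handling (0.12 over 24), nuclear-encoded oxidative phosphorylation (0.07 over 40) and sterol and fatty acid synthesis (0.12 over 28) were higher with camera adjusted p of 1.62e-04, 0.00854, 0.00416 and 0.0412. With an estimated correlation the adjusted p was 0.375, 0.351, 0.669 and 0.375. None of their members passed over all genes by edgeR, and 1, 4, 0 and 1 were higher adjusted over the list alone. Ehhadh, a peroxisomal enzyme gene, had a fold change of 1.25 (adjusted p = 0.105). Atp2a2 was at 16274 ± 707 CPM in TTg_HF (0.22, SE 0.05, adjusted p = 0.108), and Scd4, a stearoyl-CoA desaturase gene, at 13.1 ± 4.62 against 2.13 ± 1.83 (2.66, SE 0.50, adjusted p = 0.0940). The endoplasmic reticulum stress list was lower with a median of -0.14 (camera adjusted p = 0.00557, and adjusted p = 0.508 with an estimated correlation). Of 21 members 0 passed over all genes by edgeR and 1 adjusted over the list alone, Atf4 (-0.65, adjusted p = 0.127). The sterol list lost its camera call without Ctrl_HF replicates 1 and 3 (0.113 and 0.227) and TTg_HF replicates 1 and 3 (0.0630 and 0.0539), and the endoplasmic reticulum list without TTg_HF replicate 3 (0.0579). The median of the latter was -0.24 and -0.22 without Ctrl_HF replicates 1 and 3 and -0.23 without TTg_HF replicate 1. Medians of the calcium, oxidative phosphorylation and sterol lists were 0.08, 0.11 and 0.08 without TTg_HF replicate 1. The calcium median was 0.07 without Ctrl_HF replicate 2, and that of fatty acid oxidation 0.17 without Ctrl_HF replicate 1.

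The other biology lists did not pass camera, with adjusted p of 0.236 for glycolysis, 0.155 for ketone and branched-chain amino acid catabolism, 0.904 for nitric oxide signalling, 0.421 for the sarcomere, 0.901 for other cardiac transcription factors, 0.0719 for interferon response, 0.2001 for oxidative stress and 0.0765 for cell cycle. Median and mean had opposite signs for nitric oxide signalling (-0.03 and 0.04) and other cardiac transcription factors (-0.01 and 0.01). Adjusted over the list alone 2 glycolysis genes, 2 sarcomere genes and 5 oxidative stress genes were lower, among them Slc2a1 (-1.16), Des (-0.54) and Srxn1 (-1.06), none past the threshold over all genes by edgeR. Interferon response passed camera without Ctrl_HF replicate 1 (2.56e-05), cell cycle without Ctrl_HF replicate 2 (0.0166) and TTg_HF replicate 3 (0.00453), glycolysis without Ctrl_HF replicate 2 (0.0488), oxidative stress without Ctrl_HF replicate 3 (0.0332) and ketone catabolism without TTg_HF replicate 1 (0.00286).

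Technical and cell type lists differed in the same contrast. Heat shock genes had a median of -0.88 over 13 members, with none past the threshold over all genes by edgeR and 9 lower adjusted over the list alone (camera adjusted p = 2.15e-07, and adjusted p = 0.351 with an estimated correlation). The inducible chaperone gene Hspa1a, which shares sequence with Hspa1b, was at 32.5, 60.7 and 23.5 CPM in the Ctrl_HF libraries and at 5.56, 3.999 and 0.820 in TTg_HF (-3.51, SE 1.03, adjusted p = 0.210). Epicardial and mesothelial (median -0.67, adjusted p = 0.0148), neutrophil and mast cell (-1.50, 0.00363), erythroid (-0.82, 2.80e-04), skeletal muscle (-0.34, 0.0268) and ribosomal protein (-0.12, 0.00854) lists were lower by camera. Their adjusted p was 0.351, 0.351, 0.453, 0.375 and 0.772 with an estimated correlation. No member of these 5 lists passed over all genes by edgeR, and 1, 3, 0, 1 and 0 were lower adjusted over the list alone. The lowest-p members were Clic5 (-0.78), S100a9, Slc4a1 (-1.24), Acta1 (-1.50), which the stressed heart also expresses, and Rpl3 (-0.56). Erythroid genes took 0.0807%, 0.0894% and 0.0942% of counts in Ctrl_HF replicates 1, 2 and 3 and 0.0206%, 0.0867% and 0.0370% in TTg_HF. Skeletal muscle lost its call without Ctrl_HF replicates 1 and 3 (0.0705 and 0.0597) and TTg_HF replicate 1 (0.0796), and ribosomal proteins without Ctrl_HF replicate 2 (0.337) and TTg_HF replicate 1 (0.1003). Medians were -0.02 for ribosomal proteins without Ctrl_HF replicate 2, -0.21 for skeletal muscle without Ctrl_HF replicate 3, -1.07 for the epicardial list without TTg_HF replicate 2, and -0.45 and -1.64 for the erythroid list without TTg_HF replicates 1 and 2. With no filter the neutrophil and mast cell list (-0.63, adjusted p = 0.124) and the skeletal muscle list (-0.24, 0.124) lost their calls.

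Ventricular cardiomyocyte, macrophage and endothelial lists had camera adjusted p of 0.219, 0.846 and 0.336 in that contrast, and the macrophage list a median of -0.03 and a mean of 0.06. The atrial list, which holds Tbx5, had a median of -0.25 and a mean of 0.10 (adjusted p = 0.655). The Schwann cell and nerve list had a median under 0 and a mean over 0 (adjusted p = 0.864), and the clock list a median of -0.06 and a mean of 0.06 (adjusted p = 0.429). Adjusted p was 0.1004 for lymphatic endothelium, 0.490 for smooth muscle, 0.655 for pericytes, 0.655 for adipocytes, 0.490 for immediate early genes, 0.274 for mitochondrially encoded genes and 0.771 for the sex chromosome genes. Lymphatic endothelium passed without Ctrl_HF replicate 2 (0.0156) and mitochondrially encoded genes without Ctrl_HF replicate 3 (0.0437). Immediate early genes passed upward without Ctrl_HF replicate 2 (0.0269) and TTg_HF replicate 3 (0.0114), and downward without Ctrl_HF replicate 3 (0.0167).

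**Figure D3:**
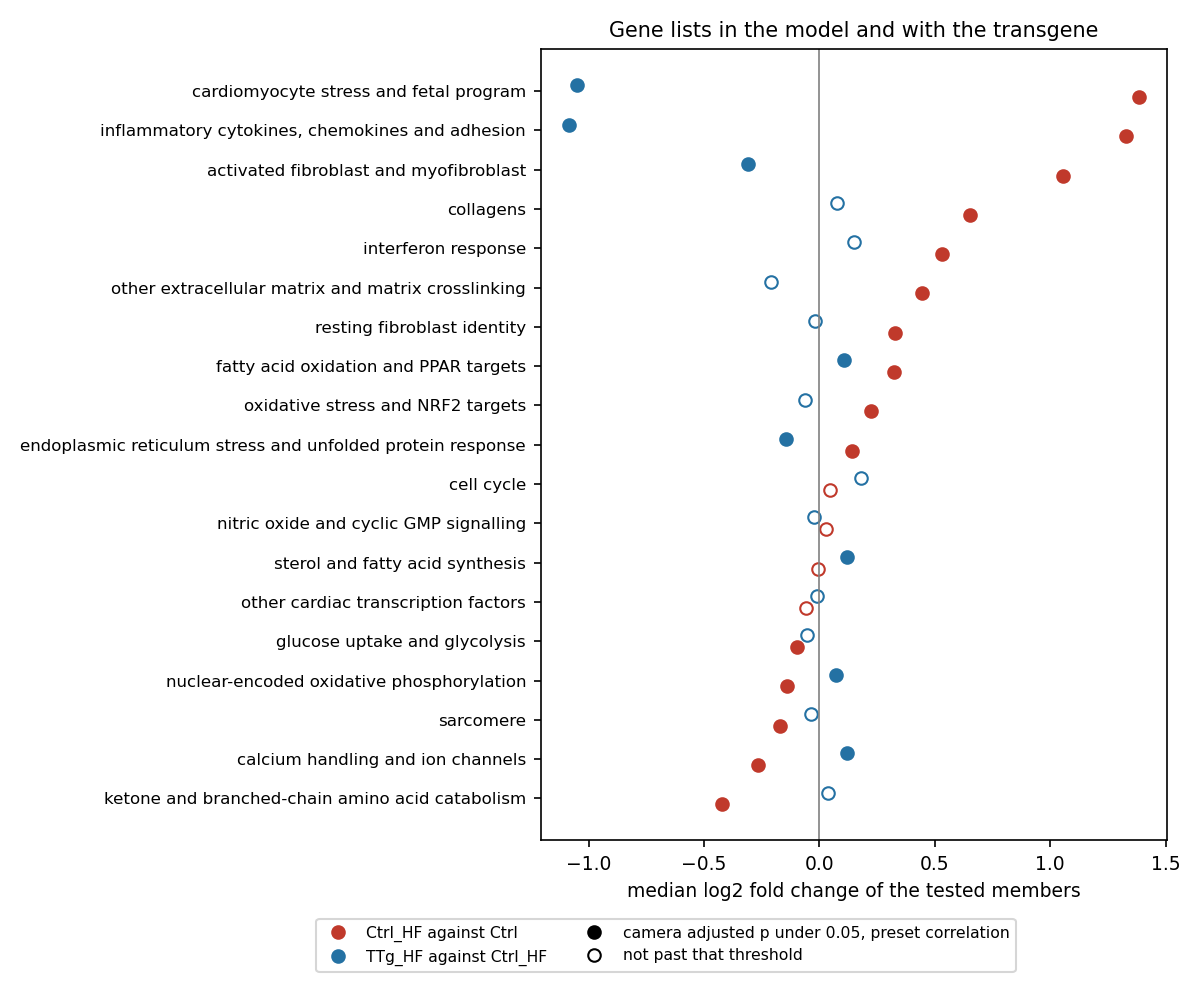
Median log2 fold change (horizontal axis) of the tested members of each of the 19 biology lists in Ctrl_HF against Ctrl (red) and TTg_HF against Ctrl_HF (blue), filled where camera with a preset correlation gave an adjusted p under 0.05. The stress list sat at 1.38 and -1.05, the inflammatory list at 1.33 and -1.08, collagens at 0.65 and 0.08, and fatty acid oxidation at 0.32 and 0.11.

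Genes changed by the model were then followed into TTg_HF. The genes called in both contrasts were 6, all in opposite directions: Lox, Cyp1b1 (1.37 in the model) and Slc7a1 (0.52) rose in the model and fell with the transgene, and Ky, Scn4a (-0.84) and Mlf1 (-1.59) did the reverse. With the replicate number as a block Lox (0.0690), Cyp1b1 (0.0665), Slc7a1 (0.0545), Scn4a (0.0692) and Mlf1 (0.0665) lost their call with the transgene, and of the 6 Ky kept it. Both contrasts contain the 3 Ctrl_HF libraries, and groups simulated with the model effect and no transgene effect shared a mean of 0.360 genes called in opposite directions (highest 2), with a mean of 1188 called in the model. Of the 458 genes called in Ctrl_HF against Ctrl, 409 (89.3%, Wilson 95% interval 86.1% to 91.8%, which treats genes as independent) had the opposite sign in TTg_HF against Ctrl_HF, 195 of 227 risers and 214 of 231 fallers. Among 20 assignments of the 6 model libraries to the labels Ctrl_HF and TTg_HF, 2 gave as high a share, the real one and 1 other. Simulated groups with no effect, which share libraries in the same way, gave 90.4%, over 458 genes each. Groups simulated with the model effect alone gave 67.7% (highest 70.4%), but called a mean of 1188 genes. Neither gene number nor model response was matched. Across genes, which are not independent replicates, the fold changes had r = -0.67 against -0.51 and -0.27 in these simulations. The covariance was -0.125 against -0.0393 and -0.0392. The simulations gave all groups 1 spread per gene and no correlation between genes. Between the Ctrl_HF libraries counts differed by a chi-square per degree of freedom of 15.6 to 23.9. In TTg_HF it was 4.53 to 8.34 and in Ctrl 5.76 to 13.6. The simulated covariances and shared calls may therefore understate chance. When 458 genes were chosen with 2 Ctrl_HF libraries and compared with TTg_HF through the remaining one, 68.1%, 72.5% and 77.7% had the opposite sign for Ctrl_HF replicates 1, 2 and 3. Of the genes that passed an adjusted p under 0.05 with those 2 libraries it was 438 of 644 (68.0%), 46 of 72 (63.9%) and 3 of 5 (60%). In these splits, chosen after seeing the data, 92.9% of the 14 stress genes had the opposite sign each time, and 28.1%, 18.8% and 25% of the 32 fatty acid oxidation genes.

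The third comparison, TTg_HF against Ctrl, shows what separated transgenic animals in the model from chow-fed controls, with diet and genotype changed together. Pdk4 was at 2876 ± 363 CPM in TTg_HF (2.41, SE 0.27, adjusted p = 0.0112). Decr1, an auxiliary enzyme of unsaturated fat oxidation, was at 677 ± 35.0 against 353 ± 35.8 in Ctrl (0.94, SE 0.08, adjusted p = 7.26e-04). Abat was at 5.02 ± 2.09 CPM (-3.63, SE 0.23, adjusted p = 1.76e-04), and Ky, at 20.02 CPM, was lower than in Ctrl (-0.99, SE 0.13, adjusted p = 0.00707). Tbx5 rose against Ctrl as well (2.32, SE 0.21, adjusted p = 0.00234). Of 12670 genes 36 rose and 23 fell, and 1192 had an unadjusted p under 0.05. The total of 59 was 24 and 29 without Ctrl replicates 2 and 3, 114 without Ctrl_HF replicate 1, and 24 and 29 without TTg_HF replicates 2 and 3. Of these 59 genes 50 were called in the same direction in Ctrl_HF against Ctrl, 29 higher and 21 lower. Both contrasts contain the 3 Ctrl libraries. In both 94.1% of the 458 genes had the same sign, against 89.5% in simulated groups with no effect and 99.7% with the model effect alone. The covariance was 0.0837, against 0.0372 and 0.244. The simulated model effect called a mean of 1188 genes rather than 458. Its 99.7% and 0.244 are unmatched and do not measure a transgene effect.

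Fatty acid oxidation had 13 of 32 members higher and 1 lower over all genes, and 26 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.17e-33). Its adjusted p was 0.0218 with an estimated correlation, which no other of the 38 lists passed in any of the 3 comparisons. Ketone and branched-chain amino acid catabolism was lower (camera adjusted p = 7.00e-14, and adjusted p = 0.133 with an estimated correlation). Over all genes 6 of 20 members fell, Bdh1 (-0.92), Ivd (-0.86), Bckdhb (-0.83), Oxct1 (-0.69), Ppm1k (-0.69) and Acadsb (-0.67), and 13 were lower and 1 higher adjusted over the list alone. Sarcomere and calcium handling lists were lower with medians of -0.19 and -0.18, camera adjusted p of 9.99e-09 and 7.46e-06, and adjusted p of 0.0512 and 0.0589 with an estimated correlation. Each had 1 member lower over all genes, Myl3 (-0.42) and Kcnip2 (-0.85), and 8 and 1 adjusted over the list alone. Glycolysis was lower (camera adjusted p = 1.99e-08, and adjusted p = 0.156 with an estimated correlation), with Eno3 (-0.58) called over all genes and 5 adjusted over the list alone. Oxidative phosphorylation was lower with a median of -0.09 (camera adjusted p = 2.37e-04, and adjusted p = 0.466 with an estimated correlation) and no member called over all genes by edgeR or adjusted over the list alone, and this call was lost without Ctrl replicate 3 (0.0806). Its median was -0.06 without TTg_HF replicate 1.

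Collagens, other matrix, activated fibroblast and resting fibroblast lists were higher than in Ctrl with medians of 0.37, 0.29, 0.26 and 0.27 (camera adjusted p = 1.99e-08, 3.57e-06, 0.00249 and 0.00432). Each had an adjusted p of 0.232 with an estimated correlation. None of their members passed over all genes by edgeR, and 5, 6, 1 and 0 were higher adjusted over the list alone, Col1a1 among them (0.76, SE 0.19, adjusted p = 0.175). The stress list had a median of -0.07 (camera adjusted p = 0.912) with no member past the threshold over all genes by edgeR or adjusted over the list alone. Without TTg_HF replicate 1 the activated fibroblast list had an adjusted p of 0.0624, the highest of its 17 alternatives with the preset correlation, and a median of 0.07. The collagen median was 0.63 and 0.24 without Ctrl replicates 1 and 2 and 0.20 without TTg_HF replicate 1. The median of other matrix genes was 0.14 without Ctrl replicate 2 and 0.18 without TTg_HF replicate 1, and the resting fibroblast median 0.14 without Ctrl replicate 1.

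The inflammatory list had a median of 0.30 (camera adjusted p = 0.0353, and adjusted p = 0.548 with an estimated correlation) and no member past the threshold over all genes by edgeR or adjusted over the list alone. This call was lost without Ctrl replicate 2 (0.235) and TTg_HF replicates 1 and 2 (0.256 and 0.0912), and the median was 0.46 without TTg_HF replicate 3. Interferon response was higher with a median of 0.68 (camera adjusted p = 1.89e-09, and adjusted p = 0.314 with an estimated correlation), with Oas2 (1.27) called over all genes and 2 members adjusted over the list alone. Macrophage markers were higher with a median of 0.41 (camera adjusted p = 1.16e-07, and adjusted p = 0.156 with an estimated correlation), with Mrc1 (0.61) called over all genes and 6 adjusted over the list alone. Ventricular cardiomyocyte markers were lower with a median of -0.22 (camera adjusted p = 8.11e-05, and adjusted p = 0.260 with an estimated correlation), 1 lower and 1 higher over all genes and 9 lower and 1 higher adjusted over the list alone. Adipocyte (median 0.57, camera adjusted p = 4.33e-04), ribosomal protein (0.12, 1.58e-04) and mitochondrially encoded (0.20, 0.00132) lists were higher, and neutrophil and mast cell (-0.76, 0.0353), erythroid (-0.15, 0.0283) and heat shock (-0.40, 0.0194) lists lower. Their adjusted p was 0.156, 0.501, 0.466, 0.314, 0.534 and 0.493 with an estimated correlation. Members called over all genes were 1 adipocyte gene, Cidea (0.93), and none of the other 5 lists by edgeR. Without Ctrl replicate 1 the medians were 0.06 for ribosomal, 0.05 for mitochondrial, -0.27 for erythroid and -0.21 for heat shock genes. They were 0.38 and -0.08 for mitochondrial and erythroid genes without Ctrl replicate 2, and 0.20, -1.19 and -0.21 for ribosomal, neutrophil and heat shock genes without Ctrl replicate 3. The erythroid median was 0.18, -0.99 and -0.09 without TTg_HF replicates 1, 2 and 3, and the heat shock median -0.26 without the third. With no filter the adipocyte list reversed to a median of -0.91 (adjusted p = 0.668). Adjusted over the list alone 4 adipocyte genes were higher and 1 lower, and 1 ribosomal protein gene was lower. Of the lists that did not pass, endoplasmic reticulum stress had a median of -0.02 and a mean of 0.07 (adjusted p = 0.755), and other cardiac transcription factors an adjusted p of 0.0550.

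Several list calls against Ctrl rested on single libraries. Without Ctrl replicate 1 the adjusted p was 0.240 for mitochondrially encoded genes, 0.05003 for ribosomal proteins, 0.209 for neutrophils and mast cells and 0.192 for heat shock. Heat shock also lost its call without Ctrl replicate 3 (0.129) and TTg_HF replicate 3 (0.148), and neutrophils and mast cells without TTg_HF replicates 2 and 3 (0.0615 and 0.179). The erythroid list lost its call without Ctrl replicates 2 and 3 (0.140 and 0.0706) and TTg_HF replicates 1 and 3 (0.965 and 0.0596), and its median without TTg_HF replicate 1 was 0.18. Other cardiac transcription factors passed downward without Ctrl replicate 2 (0.0325), Ctrl_HF replicates 1, 2 and 3 (0.0296, 0.0471 and 0.0394) and TTg_HF replicate 1 (0.0266), and pericytes without TTg_HF replicate 1 (0.0163). Endothelial (0.00760), immediate early (0.0398) and cell cycle (0.0475) lists passed upward without TTg_HF replicate 3.

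AA465934 and Myo19 also fell against Ctrl (-3.89, SE 0.38, adjusted p = 0.00310, and -1.21, SE 0.21, adjusted p = 0.0270), and both lie on chromosome 11 (GRCm38, GENCODE vM21). AA465934 is annotated as a processed transcript at 83291699 to 83294632 and overlaps the small nucleolar RNA gene Snord7 on the same strand. Myo19, a protein-coding gene at 84880148 to 84911226, overlaps Pigw and Znhit3 on the opposite strand, and reads of such pairs can be separated only if counting used strand, which is not given in the sources used here. Tbx5 lies on chromosome 5 (119832668 to 119885219), Mef2c on 13 (83504034 to 83667080), Gata4 on 14 (63198922 to 63271692) and Hand2 on 8 (57320983 to 57324633). Of 99 located named genes 40 overlap an annotated gene on the opposite strand, Lox, Atp2a2, Mlf1, Hand2 and Tcf21 among them.

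**Figure D4:**
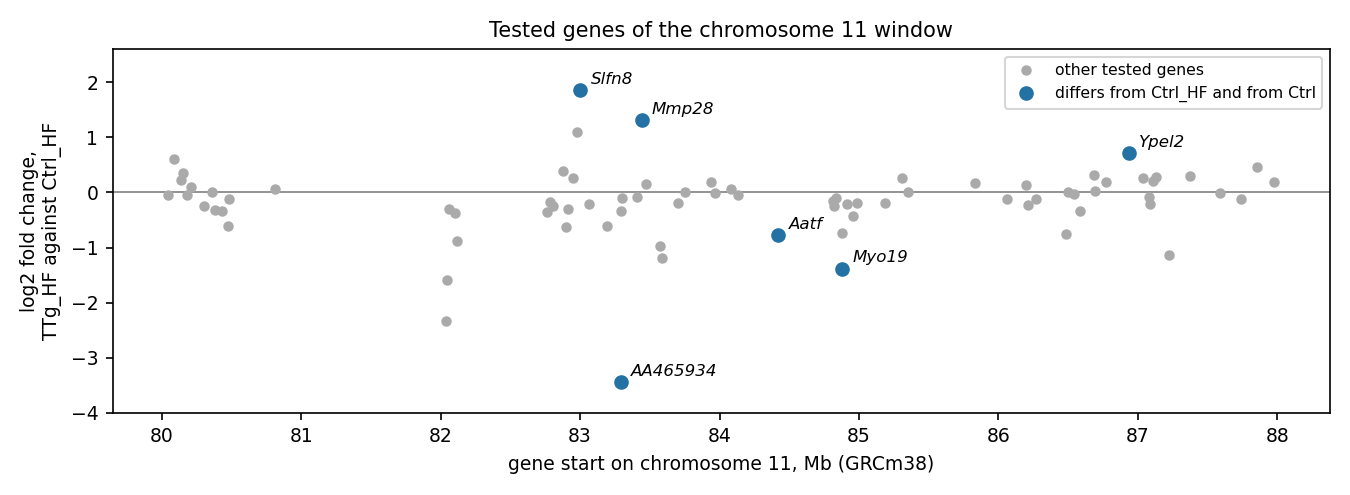
Log2 fold change in TTg_HF against Ctrl_HF (vertical axis) of the 79 tested genes between 80000001 and 88000000 on chromosome 11 (horizontal axis, gene start in Mb, GRCm38), each point a gene, with genes that differed from both other groups in blue (unadjusted p under 0.01 against Ctrl_HF and 0.05 against Ctrl). These 6, chosen after their values were seen, were Slfn8 (1.86), AA465934 (-3.45), Mmp28 (1.32), Aatf (-0.77), Myo19 (-1.38) and Ypel2 (0.72).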

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

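Added after seeing the data were the authors' factors and the comparison with no library in common. Under DESeq2's size factors and the authors' factors the comparisons called 463, 11 and 59, and 439, 12 and 53 genes, in the order Ctrl_HF against Ctrl, TTg_HF against Ctrl_HF and TTg_HF against Ctrl. The Wald test of DESeq2 gave 460 higher and 381 lower, 104 and 235, and 103 and 79, and Mef2c (0.75) and Gata4 (0.59) passed in TTg_HF against Ctrl_HF. With no filter the second comparison gave 47 higher and 62 lower and the third 67 and 51, and Mef2c (0.75) and Gata4 (0.59) passed again. List medians reversed for adipocytes in Ctrl_HF against Ctrl (-0.76) and TTg_HF against Ctrl (-0.91) and reached 0.00 for neutrophils and mast cells in TTg_HF against Ctrl, where genes near 0 counts enter the lists. Fits of the 6 libraries compared gave 58 and 68, 0 and 0, and 70 and 47. In the second of these edgeR had 1624 genes at an unadjusted p under 0.05, with 339 called by DESeq2 and 8 by limma-voom in all 9 libraries, and Tbx5 had a fold change of 2.59 (adjusted p = 0.0600, against 4.94e-30 to 0.0600 over its alternatives). The opposite share was then 81.7%. Limma-voom gave 3 lower in the second comparison and the replicate block 15 lower in the third. At an adjusted p under 0.1 there were 512 and 470, 43 and 37, and 72 and 50, and at a fold of at least 1.5 there were 146 lower in the first comparison. With no library in common the opposite share was 68.1%, 72.5% and 77.7% of 458 genes with the lowest p, and 68.0%, 63.9% and 60% of the 644, 72 and 5 that passed. Camera with an estimated correlation passed 0 lists higher and 0 lower in the first and second comparisons, and 1 and 0 in the third. The preset correlation passed 16 and 6, 4 and 10, and 11 and 9. Fry passed 10 higher and 7 lower in the first, 0 and 0 in the second, and 2 and 4 in the third comparison. Leaving out 1 library gave 28 to 660 higher and 57 to 462 lower in the first comparison, lowest without Ctrl replicate 2 (28 and 57) and highest without Ctrl_HF replicate 1 (660 and 462). It gave 2 to 220 higher and 0 to 445 lower in the second, highest without Ctrl_HF replicate 1 (220 and 445) and lowest without TTg_HF replicate 2 (2 and 0, with 1270 at an unadjusted p under 0.05). The third comparison gave 13 to 70 higher and 11 to 44 lower. The other totals that moved by over 1.5 times were, in the first comparison, 293 and 142 without Ctrl replicates 1 and 3, 257 and 152 without Ctrl_HF replicates 2 and 3, and 224 and 304 without TTg_HF replicates 2 and 3. In the second they were 5 without Ctrl replicate 2, 18 and 3 without Ctrl_HF replicates 2 and 3, and 26 and 5 without TTg_HF replicates 1 and 3. In TTg_HF against Ctrl they were 114 without Ctrl_HF replicate 1, and 24 and 29 without replicates 2 and 3 of either Ctrl or TTg_HF. Lists passing ranged from 12 to 17 higher and 6 to 8 lower, 4 to 6 and 8 to 11, and 9 to 14 and 6 to 10. The opposite share ranged from 80.0% to 95.5%, and the fold changes in TTg_HF against Ctrl_HF from 2.35 to 2.79 for Tbx5, 0.58 to 0.86 for Mef2c, 0.50 to 0.65 for Gata4 and 0.44 to 0.66 for Hand2. Gata4 in Ctrl_HF against Ctrl ranged from -0.179 to 0.0597 and reversed without Ctrl replicate 1 (0.0597). Tcf21 in TTg_HF against Ctrl_HF ranged from -0.0184 to 0.165 and reversed without Ctrl_HF replicate 1 (-0.0184). Without Ctrl_HF replicate 3 immediate early genes reversed to 0.36 in Ctrl_HF against Ctrl (lowest -0.29 with 1 library left out and -0.34 over all alternatives) and to -0.22 in TTg_HF against Ctrl_HF (highest 0.44). Where not given by fewer libraries, another threshold or added genes, the cause was not tested. Over the alternatives that keep the preset correlation list results kept their side of the threshold, and where called their direction, in 1829 cases. The call was lost in 50, gained in 48 and reversed in 5. Direction was not compared for lists called in neither setting. Their medians could change sign, as for macrophages in TTg_HF against Ctrl_HF (-0.160 to 0.130). Named genes kept direction and side of the threshold over all their alternatives in 1821 cases, lost the call in 170, gained it in 112 and reversed in 2. The stress, fatty acid oxidation and inflammatory lists in the first 2 comparisons kept direction and camera call in all 17 alternatives that keep the preset correlation, as did calcium handling, heat shock and epicardial lists there and collagens in both comparisons with Ctrl. At this depth, with 3 libraries per group and 1 simulated spread for all groups, 27.1% of simulated 1.5-fold changes were recovered in TTg_HF against Ctrl_HF. Which of depth, number and spread of libraries limits this was not tested.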

Other observations

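Chosen only after the results were seen were all tests below except those of neighbouring genes and of other splits for Ctrl_HF against Ctrl and TTg_HF against Ctrl, and so were the genes of the next 2 paragraphs. Some further genes rose against Ctrl in both model groups. Acsf2, an acyl-CoA synthetase gene, was at 29.5 ± 4.35 CPM in Ctrl, 54.3 ± 4.32 in Ctrl_HF and 57.7 ± 4.91 in TTg_HF (n = 3 each; log2 fold changes against Ctrl of 0.88 and 0.96). Ephx2, the soluble epoxide hydrolase gene, was at 229 ± 20.7, 344 ± 39.2 and 385 ± 11.3 CPM (0.58 and 0.75), and Pex11a, a gene of peroxisome proliferation, rose by 0.85 and 0.88. Fbp2, the muscle fructose bisphosphatase gene, rose by 0.88 and 1.22, the acyl-CoA binding protein gene Dbi by 0.74 and 0.74, Hsd17b11, which encodes a lipid droplet enzyme, by 1.00 and 1.45, and the nicotinic receptor subunit gene Chrna2 by 2.13 and 2.35. The phospholipid enzyme gene Lpcat3 (0.43 and 0.65) rose as well.

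Other genes fell against Ctrl in both model groups. Pcx, the pyruvate carboxylase gene, was at 46.1 ± 2.74 CPM in Ctrl, 27.4 ± 4.05 in Ctrl_HF and 24.1 ± 1.82 in TTg_HF (-0.75 and -0.93). Gcdh, which acts in lysine breakdown, was at 48.3 ± 4.29, 27.8 ± 2.37 and 29.2 ± 1.60 CPM (-0.79 and -0.73). Ogdhl, a relative of oxoglutarate dehydrogenase, had fold changes of -0.89 and -1.39, and Gstk1, a glutathione transferase gene, of -0.80 and -0.80. Epn3, an endocytic adaptor gene, was at 44.7 ± 9.98, 19.3 ± 6.26 and 8.91 ± 0.541 CPM (-1.20 and -2.32). In TTg_HF against Ctrl_HF it had a fold change of -1.13 (adjusted p = 0.108 by edgeR), the lowest adjusted p there among the genes of these 2 paragraphs.

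Splits of the 6 libraries of each comparison into other groups of 3 called fewer genes: 1 of 10 splits, the real one, gave as many in each comparison. The real split called 458 genes in Ctrl_HF against Ctrl and the highest other 2, in TTg_HF against Ctrl_HF 11 and 2, and in TTg_HF against Ctrl 59 and 1. With 10 splits a share under 0.05 cannot be reached.

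Over all tested genes the log2 fold changes with the model and with the transgene ran in opposite directions. Their covariance was -0.125, against -0.0393 in simulated groups with no effect and -0.0392 in groups with the model effect alone. These simulations gave all groups 1 spread, while the Ctrl_HF libraries differed more from each other, so they may understate chance. Of the 458 genes called in the model 89.3% had the opposite sign, against 90.4% in simulated groups with no effect. Groups with the model effect alone gave 67.7%, but over an unmatched mean of 1188 genes. The shared Ctrl_HF libraries alone are argued against only weakly as the whole source. With no library in common the mean covariance was still -0.0654 (SD 0.0226 over 3 splits, all 3 below 0). These splits reuse the same Ctrl and TTg_HF libraries and overlap in Ctrl_HF libraries. Their SD and common sign therefore do not measure the uncertainty of that mean. Spread between individual animals of the model stays open: 1 of 20 assignments of the 6 model libraries, the real one, gave a mean covariance as negative (-0.0606, most negative other -0.0409). With 20 assignments a share under 0.05 cannot be reached. The opposite share over 458 genes, with the Ctrl_HF libraries shared, reached 89.3% in 2 of the 20. The other had TTg_HF replicate 1 in place of Ctrl_HF replicate 1. A partial reversal of the model's response by the transgene stays a hypothesis beside that spread.

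Macrophage and endothelial markers were higher and ventricular cardiomyocyte markers lower in Ctrl_HF than in Ctrl by camera with the preset correlation, but not with an estimated one (adjusted p = 0.268, 0.382 and 0.268), and smooth muscle, pericyte and Schwann cell lists passed neither. A lower share of cardiomyocytes would raise the markers of every other type alike, and the mean log2 fold changes were 0.45 for macrophages, 0.31 for smooth muscle, 0.15 for endothelium, 0.12 for Schwann cells and -0.15 for pericytes. Their largest gap, 0.599, was reached in a share of 0.0796 of 10000 shufflings of the markers among the lists (95th percentile 0.644), so that a lower share may contribute and cannot be told apart from changes within cells. The most abundant markers were at 349 and 365 CPM in Ctrl and Ctrl_HF for endothelium (Ptprb), 107 and 116 for macrophages (Lyz2), 1518 and 2307 for smooth muscle (Des, which cardiomyocytes also express), 772 and 529 for pericytes (Abcc9, also expressed in cardiomyocytes) and 8.55 and 7.91 for Schwann cells (Cnp). Acta2, Tagln and Cnn1 of the smooth muscle list also belong to the activated fibroblast list, and a change in cell number or in expression with the diet stays untested.

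Genes that differed in TTg_HF from both other groups lay together on chromosome 11: of 88 such genes (unadjusted p under 0.01 against Ctrl_HF and 0.05 against Ctrl) 6 lay between 80000001 and 88000000, among 79 tested genes, while the fullest window of shuffled positions held a median of 3. Slfn8, Mmp28 and Ypel2 had log2 fold changes against Ctrl_HF of 1.86, 1.32 and 0.72 and AA465934, Myo19 and Aatf of -3.45, -1.38 and -0.77, of which AA465934 and Myo19 passed. Regulation of neighbouring genes stays open: the fullest windows of the 425 and 592 genes that set Ctrl or Ctrl_HF apart were matched in shares of 0.368 and 0.942 of shufflings, but sets of that size can hide such a group, as 196 genes did for TTg_HF in windows of 8 Mb. Chance position also stays open: a window as full came in a share of 0.00980 of 10000 shufflings, but in 0.408 and 0.410 with 196 genes at an unadjusted p under 0.05 in windows of 4 and 8 Mb (0.0320 at 16 Mb), where at 8 Mb the fullest window was on chromosome 1, and in 0.0180, 0.0125 and 0.0185 of 2000 shufflings with the 88 genes in windows of 4, 8 and 16 Mb. Strain alleles carried with the transgene on this hybrid background may also account for it, but that the TTg_HF libraries lay outside the other 6 for 6 of 6 genes decides nothing, since these genes were chosen for differing, and neither the insertion site nor sequence variants were analysed here.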
